A study of Mus musculus with 16 samples.

How the data were processed

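RNA sequencing of mouse liver was analysed in 16 libraries, 4 from each of 4 diet groups. Per the series' design text, male C57BL/6 mice received the diets for 16 weeks in groups of 6, livers were taken after a night without food, and only RNA of high integrity was sequenced. The design text states that reads were aligned with HISAT2 to the mm10 mouse genome, that expression was calculated as FPKM with RSEM 1.1.17 on Ensembl annotation, and that edgeR 3.14.0 compared pairs of groups at a false discovery rate of 0.05 and a fold change of 2. The deposited gene and transcript tables hold TPM, a unit scaled to a fixed sum, rather than FPKM, because each column summed to 1000000. The submitters' processing notes were not more specific about the conversion. A gene's deposited TPM equalled the sum over its transcripts to within 9e-06 TPM. TPM keeps no sequencing depth, so the depth of each library is unknown and no interval that needs counts is given. Libraries are compared by the share of each transcript among all transcripts, and a gene that takes a larger share lowers the TPM of every other gene. The labels do not say whether each library came from its own animal, so the p-values measure the spread between these samples.

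The deposited values covered 22612 genes and 97455 transcripts, under Ensembl identifiers. Gene symbols and positions were taken by identifier from GENCODE vM21 on GRCm38 (mm10), in which 22582 gene identifiers (99.87%) were found, 21928 of them protein-coding. Start and end of 94888 transcripts equalled that annotation. All 16 columns of each table were matched to samples by name.

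The test chosen beforehand for FPKM was applied to TPM, a unit the plan had not foreseen. Values were transformed as log2(TPM + 1), genes with at least 1 TPM in at least 4 of the libraries of a comparison were kept, and limma 3.58.1 in R 4.3.3 was fitted with an intensity trend to the 8 libraries of each comparison, without covariates. P-values were adjusted by Benjamini-Hochberg. A gene was called at an adjusted p below 0.05 and a fold change of at least 2. Members of gene lists were said to have changed at an adjusted p below 0.05 with no fold limit, over all genes tested and, separately, adjusted over the list alone. Fold changes are on the log2(TPM + 1) scale and understate the change of genes near 1 TPM. Reads of near-identical genes, such as the Gsta, Gstm, Saa, Mup, Cyp2b, Cyp2c, Cyp3a and Hba families, were divided between the copies by estimation, so the split within such a family is uncertain.

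The comparisons, tests, 23 gene lists, 12 sets of cell type markers and the rule for naming genes were fixed before the data were examined. The lists covered de novo lipogenesis, malonyl-CoA and malonylation, triglyceride storage and lipid droplets, fatty acid oxidation and PPAR alpha targets, ketone body metabolism, cholesterol synthesis, bile acid synthesis and transport, lipoproteins and sterol export, gluconeogenesis and fasting, glycolysis and sugar metabolism, amino acid catabolism and urea cycle, oxidative phosphorylation, endoplasmic reticulum stress and integrated stress response, NRF2 and glutathione, xenobiotic P450 enzymes, male-biased liver genes, acute phase response, cytokines and adhesion molecules, interferon response, collagen and fibrosis, cell cycle, circadian clock, and immediate early and heat shock genes. The markers stood for hepatocytes, resident macrophages (Kupffer cells), recruited and lipid-associated macrophages, T and NK cells, B and plasma cells, neutrophils, stellate cells, sinusoidal endothelial cells, cholangiocytes, adipocytes, exocrine pancreas and red blood cells. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with a correlation estimated from the data, and with fry, and adjusted over the 35 sets of each comparison. Camera compares a list with all other genes, whereas fry asks whether the members move 1 way on balance. Named genes were, for each of 4 main comparisons, up to 8 higher and 8 lower called genes of largest fold change whose groups did not overlap and whose mean over the 8 libraries was at least 1 TPM, leaving out predicted genes and antigen receptor segments, and up to 4 and 4 for each of 2 secondary comparisons. To these were added up to 4 members of each list with the smallest adjusted p, or the 2 most abundant where none passed, and 8 genes of malonyl-CoA and fatty acid metabolism. Genes named outside this rule are said to be so. Single-gene results of some genes that met this rule are not reported here.

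Where comparisons shared the high-fat libraries, overlaps and correlations of fold changes were set beside 100 simulated draws without effect and beside values from fits in which the high-fat libraries were divided 2 and 2. Shares of Acaca and Acacb transcripts holding at least 5% of the gene total were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment. Alternatives chosen before the data were examined were quantile normalization, no filter on low values, a mean of at least 1 TPM, a pseudocount of 0.1, no fold limit, a fit of all 16 libraries, the replicate number as a block and each library left out in turn. Median centring, removal of each library's trend on transcript length, and leaving out the 4 libraries with over 33% of their TPM in 20 genes were added after seeing the data. Each comparison was also refitted over all 35 divisions of its 8 libraries into 4 and 4. The fits were tested on simulated values with 200 changed genes and independent noise, which is milder than the shared noise of real libraries. A gene was recovered at an adjusted p below 0.05 in the right direction with no fold limit. The share that would also reach the fold limit of a call was not counted. Of genes changed by 1 on the log2 scale, 50% were recovered in the simulation of high fat against chow, 70% in that of the chow-alternating against the high-fat group and 88% in that of the ketogenic-alternating against the chow-alternating group. Of genes changed by 2, 98%, 94% and 98% were recovered, and 6, 10 and 12 unchanged genes passed the test. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.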

Results

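Liver gene expression was measured by RNA sequencing in male C57BL/6 mice on 4 diets. Chow (11% of energy from fat) and a high-fat diet (58%) were each fed for 16 weeks. In the chow-alternating group the high-fat diet and chow took turns every 2 weeks, and in the ketogenic-alternating group the high-fat diet took turns with a ketogenic diet (90.5% of energy from fat). Each group had 4 libraries, although the labels give 6 mice per group. The labels do not say which diet the alternating groups received last before collection, nor the hour of collection. Sequencing depth is unknown, since TPM keeps none. Between 10575 and 11695 genes per library reached 1 TPM, and replicates of a group correlated across genes with r between 0.9605 and 0.9903, where genes are not independent replicates.

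Libraries differed along an axis that was not diet alone. The first principal component held 36.69% of the variance, and 4 of its relations were tested with permutation tests over the 16 libraries. It rose with the share of TPM in each library's 20 highest genes (Pearson r = 0.914, permutation p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05; Spearman rho = 0.932, p = 1e-05). This r was 0.868 without the 2 libraries farthest from the median and 0.911 for deviations from the group means. The component fell with the trend of a library's values on transcript length (r = -0.863, permutation p = 3e-05, adjusted p = 6e-05; rho = -0.838, p = 0.00015), with r = -0.852 without 2 libraries and -0.881 within groups. The share of mitochondrial genes had r = 0.726 (permutation p = 0.00055, adjusted p = 0.00073; rho = 0.659, p = 0.0063), r = 0.587 without 2 libraries and 0.725 within groups. GC content had r = 0.452 (permutation p = 0.078, adjusted p = 0.078, rho = 0.576, p = 0.022), r = 0.749 without 2 libraries and 0.467 within groups. The component and these 4 measures come from the same TPM values, which have a fixed sum. Some relation is therefore built in, and the p-values do not show a link between separate measurements. Chow replicate 3 stood highest in both the share of its 20 highest genes (38.82%) and of mitochondrial genes (18.37%).

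**Figure D1:**
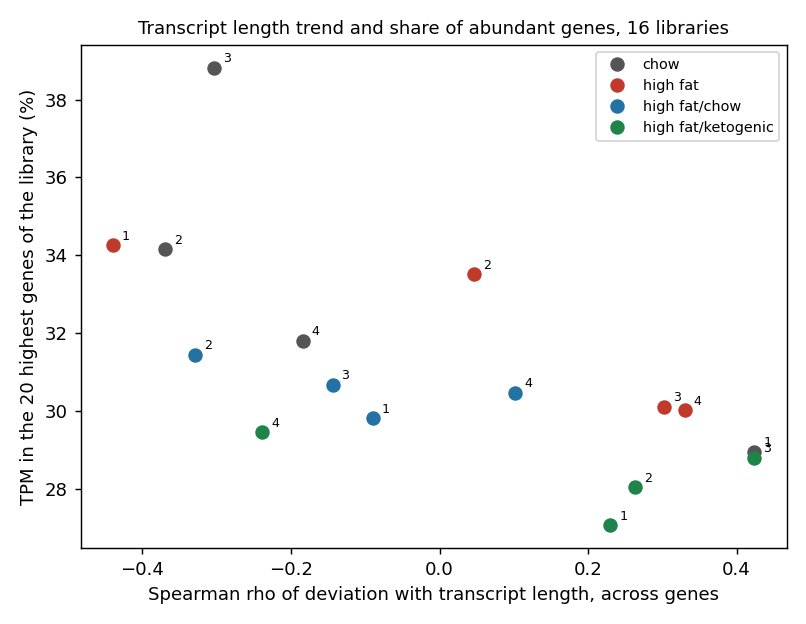
Share of TPM in the 20 highest genes of each library (percent, vertical) against the Spearman rho of its deviations with transcript length across genes (horizontal), 1 numbered point per library and 4 libraries per diet group. The share ran from 27.08% in ketogenic-alternating replicate 1 to 38.82% in chow replicate 3, and ketogenic-alternating replicates 1 to 3 lay at length rho of 0.23 or more while replicate 4 lay at -0.239.

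The comparison of the high-fat with the chow group asked what the continuous high-fat diet did to the liver transcriptome. In high-fat livers 13 of 25 members of cholesterol synthesis were higher, and 5 of 14 of NRF2 and glutathione and 5 of 16 xenobiotic P450 enzymes were lower. Camera called these 3 lists, and with an estimated correlation the calls were lost (adjusted p = 0.27, 0.27 and 0.444). Apoa4 (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459 on mm10), an apolipoprotein of triglyceride-rich particles, rose from 369 ± 151 TPM (SD, n = 4) to 3758 ± 874 TPM, a log2 fold change of 3.41 (SE 0.278, adjusted p = 7.2e-04). Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633), the rate-limiting enzyme of bile acid synthesis, rose from 3.98 ± 1.20 to 51.6 ± 36.5 TPM (adjusted p = 0.00588). Cyp2b10 (ENSMUSG00000030483, chromosome 7, 25897620 to 25926624), a P450 enzyme induced by foreign compounds, fell from 12.3 ± 6.47 to 0.684 ± 0.473 TPM (adjusted p = 0.00196). Genes named here as a largest rise or fall were taken only where all 4 libraries of a group lay on 1 side of all 4 of the other. That separation is part of the naming rule and not a further result. Among 10960 genes tested with limma, 95 were called, 54 higher and 41 lower, and 116 passed with no fold limit. Leaving out 1 library moved the count to 36 without chow replicate 4, 54 without chow replicate 2, 56 without chow replicate 3, 39 without high-fat replicate 2 and 38 without high-fat replicate 4. Without the 4 libraries that held over 33% of their TPM in 20 genes, chosen after seeing the data, 19 genes were called. In that fit of 2 against 2, of the genes named in this and the next 2 paragraphs, Cyp7a1 (log2 fold change 2.99, adjusted p = 0.124), Idi1 (3.02, adjusted p = 0.0608), Msmo1 (2.74, adjusted p = 0.0532), Selenbp2 (2.81, adjusted p = 0.223), Slc22a7 (2.25, adjusted p = 0.202), Fasn (1.501, adjusted p = 0.0701), Gsta2 (-2.15, adjusted p = 0.155), Gsta4 (-1.61, adjusted p = 0.124), Cyp3a11 (-2.27, adjusted p = 0.112) and Cyp3a25 (-1.05, adjusted p = 0.0899) lost their calls, and Cyp2b10, Gsta1 and Cyp26a1 were not tested.

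In cholesterol synthesis, 13 of 25 members rose (22 adjusted over the list alone), with a median log2 fold change of 1.51. Camera gave an adjusted p of 1.01e-33, against adjusted p = 0.27 with an estimated correlation. Fry gave adjusted p = 0.0252, as it did for NRF2 and glutathione and for P450 enzymes. The other gene lists that camera called in this comparison, marker sets apart, had fry adjusted p from 0.351 to 0.672. Msmo1, a sterol demethylation enzyme, rose from 30.4 ± 16.4 to 198 ± 81.3 TPM (log2 fold change 2.74, adjusted p = 0.00667), Mvd by 2.70 (adjusted p = 0.00296) and Sqle, the squalene epoxidase, by 2.70 (adjusted p = 0.00784). Idi1 (2.89, adjusted p = 0.0144) and Mvk (2.04, adjusted p = 0.013) lost their calls without high-fat replicate 2 or 4 or chow replicate 4, with adjusted p up to 0.0704 and 0.0619. In NRF2 and glutathione, 5 of 14 tested members fell (7 adjusted over the list alone), with a median of -0.475 and a mean of -1.11. Its camera adjusted p was 3.48e-07, with adjusted p = 0.27 with an estimated correlation. Gsta1, Gsta2 and Gsta4, which conjugate glutathione, fell by 4.39 (adjusted p = 0.00313), 2.89 (adjusted p = 0.00666) and 1.85 (adjusted p = 0.00588) on the log2 scale. Among xenobiotic P450 enzymes, 5 of 16 tested members fell (5 lower and 2 higher adjusted over the list alone), with camera adjusted p = 0.0235 and adjusted p = 0.444 with an estimated correlation. Cyp3a11, the main P450 of drug metabolism, fell from 4115 ± 800 to 890.2 ± 357 TPM (adjusted p = 0.00557) and Cyp3a25 fell by 1.00 (adjusted p = 0.00705). Cyp26a1, which degrades retinoic acid, fell by 1.91 (adjusted p = 0.00333), and Slc39a4, a zinc importer, by 2.49 (adjusted p = 0.00196).

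The acute phase genes Saa1 (log2 fold change 3.04, adjusted p = 0.00855) and Saa2 (2.48, adjusted p = 0.00667) rose. In the acute phase response, 3 of 17 members rose (3 adjusted over the list alone), with a median of 0.0905 and a mean of 0.515, camera adjusted p = 8.13e-04 and adjusted p = 0.444 with an estimated correlation. Selenbp2, a selenium-binding protein, rose by 3.40 (adjusted p = 0.0108) and Slc22a7, an organic anion transporter, by 2.74 (adjusted p = 0.00684). In de novo lipogenesis, 1 of 19 tested members rose (3 higher and 1 lower adjusted over the list alone), with camera adjusted p = 4.94e-04 and adjusted p = 0.444 with an estimated correlation. Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), which builds fatty acids from malonyl-CoA, rose from 17.3 ± 4.69 to 44.2 ± 10.7 TPM (adjusted p = 0.0215). Its call was lost without high-fat replicate 2 or 4 or chow replicate 3 or 4, with adjusted p up to 0.105. Acaca (ENSMUSG00000020532, chromosome 11, 84129672 to 84401651), acetyl-CoA carboxylase 1, had 11.8 ± 4.33 against 8.17 ± 3.87 TPM (log2 fold change 0.49, SE 0.314, adjusted p = 0.612). Its paralog Acacb (adjusted p = 0.962), the malonyl-CoA decarboxylase Mlycd (adjusted p = 0.678), the demalonylase Sirt5 (adjusted p = 0.366), the lipogenic regulator Srebf1 (adjusted p = 0.334) and the fatty acid importer of mitochondria Cpt1a (adjusted p = 0.821) did not pass. In malonyl-CoA and malonylation, 1 of 7 members rose (1 adjusted over the list alone), with camera adjusted p = 0.0179 and adjusted p = 0.444 with an estimated correlation.

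Over all genes tested, other lists held few changed members in the high-fat group. Camera's adjusted p was 8.13e-04 for bile acid synthesis and transport (2 of 17 rose, median 0.303), 0.00395 for male-biased liver genes (1 of 13 rose, median 0.172, mean 0.646) and 1.25e-05 for interferon response (0 of 14, median 0.525). All of these had adjusted p = 0.444 with an estimated correlation. Adjusted over the list alone, 5 bile acid genes rose and 1 fell, 5 male-biased genes rose and 2 fell, and 1 interferon gene rose. Collagen and fibrosis had 0 of 13 (median 0.193, camera adjusted p = 0.0447, adjusted p = 0.722 with an estimated correlation). Lipoproteins and sterol export had 2 of 19 higher with a median of -0.129 and a mean of 0.102, and endoplasmic reticulum stress had 1 of 18 lower with a median of 0.284. The medians of lists without a changed member were -0.0417 for triglyceride storage and lipid droplets, 0.116 for fatty acid oxidation (mean -0.0756), 0.0941 for ketone body metabolism, -0.322 for gluconeogenesis and fasting, -0.142 for glycolysis and sugar metabolism (mean 0.00527), -0.0455 for amino acid catabolism, -0.0724 for oxidative phosphorylation, 0.382 for cytokines, -0.103 for cell cycle, 0.348 for circadian clock and -0.0326 for immediate early and heat shock genes, and camera called none of them. Adjusted over the list alone, 4 members of gluconeogenesis and fasting fell, and 3 of circadian clock rose and 2 fell. In the same way, 1 member of fatty acid oxidation fell, and 1 each of ketone body metabolism and of glycolysis rose. No cell type marker passed the test over all genes in this comparison. Camera called the markers of resident macrophages (median 0.483, adjusted p = 2.24e-04), T and NK cells (0.285, adjusted p = 0.0447), B and plasma cells (0.457, adjusted p = 0.0235), stellate cells (0.215, adjusted p = 0.0455), cholangiocytes (-0.508, adjusted p = 0.0285), adipocytes (0.763 over 2 tested of 7, adjusted p = 0.0188) and red blood cells (0.301, adjusted p = 0.0376). With an estimated correlation their adjusted p ranged from 0.304 to 0.647. Fry gave adjusted p = 0.0252 for the adipocyte markers and 0.205 to 0.618 for the other marker sets that camera called. The adipocyte result rests on 2 tested genes, whose correlation was estimated at -0.661, and 2 genes are too few to stand for a cell type. Medians were -0.135 for hepatocytes, -0.177 for recruited macrophages, 0.238 for neutrophils and 0.0899 for sinusoidal endothelial cells, and no marker of exocrine pancreas was tested.

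The comparison of the chow-alternating with the high-fat group asked what interrupting the high-fat diet with chow changed. Of 16 xenobiotic P450 enzymes tested, 3 were higher with the chow intervals, in a list whose camera call was lost with an estimated correlation (adjusted p = 0.142), and Apoa4 was lower. Cyp2b10 rose from 0.684 ± 0.473 to 8.62 ± 2.60 TPM (SD, n = 4; log2 fold change 2.52, SE 0.234, adjusted p = 0.00117) and Cyp2c29, another P450 enzyme, from 479 ± 69.0 to 1451 ± 299 TPM (log2 fold change 1.58, adjusted p = 0.00448). Apoa4 fell from 3758 ± 874 to 606 ± 211 TPM (log2 fold change -2.67, SE 0.248, adjusted p = 0.00117). Cyp2c55 rose by 1.51 (adjusted p = 0.0313), a call lost without high-fat replicate 1, 2 or 4, with adjusted p up to 0.188. Of 8 fits that each left out 1 library, Cyp2c55 was tested in 4 and passed in 1. It was not tested without any single chow-alternating replicate. Of 10899 genes tested, 4 were called with limma, 5 passed with no fold limit and 452 had an unadjusted p below 0.05. The gene that passed below the fold limit, Fabp2, a fatty acid binding protein chosen after its values were seen, fell by 0.92 (adjusted p = 0.0313) but failed without high-fat replicate 1 or 4 or any single chow-alternating replicate, with adjusted p up to 0.272. Leaving out high-fat replicate 3 raised the count to 29. In the fit without the libraries over 33% in 20 genes, 1 gene was called, and Apoa4 (log2 fold change -2.71, adjusted p = 0.102) and Cyp2c29 (log2 fold change 1.53, adjusted p = 0.102) were not.

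Among xenobiotic P450 enzymes, 3 of 16 tested members rose (5 adjusted over the list alone), with a median of 0.382, camera adjusted p = 4.51e-13, adjusted p = 0.142 with an estimated correlation and fry adjusted p = 0.0195. Over all genes tested, no other list had a changed member except lipoproteins and sterol export, through Apoa4. Camera called interferon response lower (median -0.462, adjusted p = 5.62e-08), endoplasmic reticulum stress higher (0.344, adjusted p = 4.52e-08), amino acid catabolism and urea cycle higher (0.225, adjusted p = 1.71e-04) and markers of resident macrophages lower (-0.48, adjusted p = 1.85e-07). With an estimated correlation their adjusted p was 0.318, 0.318, 0.58 and 0.345. It also called markers of hepatocytes higher (median 0.211, 10 of 10 above 0, adjusted p = 0.00874) and markers of sinusoidal endothelial cells (-0.137, adjusted p = 0.0189), T and NK cells (-0.292, adjusted p = 0.0322) and adipocytes (-0.543 over 2 tested, adjusted p = 0.0186) lower. With an estimated correlation these had adjusted p from 0.318 to 0.603. In cholesterol synthesis, the median was -0.257 with 0 of 25 members passing (0 adjusted over the list alone), camera adjusted p = 0.0113 and adjusted p = 0.603 with an estimated correlation. NRF2 and glutathione had 0 of 14 passing (5 higher adjusted over the list alone) and a median of 0.258, with camera adjusted p = 0.00547 and adjusted p = 0.318 with an estimated correlation. Camera further called gluconeogenesis and fasting (median 0.289, adjusted p = 0.0358), oxidative phosphorylation (0.102, adjusted p = 0.0276) and acute phase response (0.225, adjusted p = 0.0113) higher, and fatty acid oxidation (-0.127, adjusted p = 0.0179), ketone body metabolism (-0.194, adjusted p = 0.0322), cytokines (-0.308, adjusted p = 0.0136) and male-biased liver genes (-0.374, adjusted p = 0.0322) lower. With an estimated correlation these 7 had adjusted p from 0.318 to 0.603. Without the libraries over 33% in 20 genes, camera's direction turned for gluconeogenesis and fasting (median -0.00992, adjusted p = 0.956) and for male-biased liver genes (-0.114, adjusted p = 0.165), which ended both calls. Apart from P450 enzymes, the gene lists that camera called in this comparison had fry adjusted p from 0.0989 to 0.767. Of the marker sets that camera called, adipocytes had fry adjusted p = 0.0195, over only 2 tested members whose correlation was estimated at -0.86, and the others had 0.411 to 0.755. Acaca had 9.55 ± 2.09 against 11.8 ± 4.33 TPM (log2 fold change -0.23, SE 0.257), Fasn -0.27 (SE 0.253) and Srebf1 -0.48 (SE 0.296), each with adjusted p = 1 in limma.

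The comparison of the ketogenic-alternating with the high-fat group asked what ketogenic intervals changed. Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), which makes monounsaturated fatty acids, fell from 886 ± 193 TPM (SD, n = 4) to 28.3 ± 25.8 TPM, a log2 fold change of -5.24 (SE 0.421, adjusted p = 5.05e-04). Cyp2c70, which makes the muricholic acids of mouse bile, fell from 239 ± 48.2 to 63.3 ± 13.8 TPM (log2 fold change -1.90, adjusted p = 0.00343). Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655), complement factor D, rose from 1.70 ± 1.21 to 24.6 ± 13.2 TPM (log2 fold change 3.21, adjusted p = 0.0088), a call lost without high-fat replicate 1 or 2, with adjusted p up to 0.0759. Hamp2, a hepcidin peptide, fell by 2.88 (adjusted p = 0.0322) and lost its call without ketogenic-alternating replicate 2 or 3 or high-fat replicate 1 or 2, with adjusted p up to 0.189. These were the 4 genes called with limma among 11108 tested, with 1116 at an unadjusted p below 0.05. The median of all genes was 0.21 higher in the ketogenic-alternating group, and the fold changes of this comparison are to be read against that shift. Leaving out high-fat replicate 3 gave 21 calls, and leaving out high-fat replicate 1 or 2 gave 2. Without the libraries over 33% in 20 genes, Cfd (log2 fold change 3.04, adjusted p = 0.283) and Hamp2 (-2.93, adjusted p = 0.283) lost their calls.

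In fatty acid oxidation, 0 of 29 members passed over all genes and 15 were higher adjusted over the list alone, with a median of 0.49, camera adjusted p = 3.44e-08 and adjusted p = 0.318 with an estimated correlation. Triglyceride storage had 0 of 22 passing and 5 higher adjusted over the list alone, with a median of 0.385, camera adjusted p = 5.69e-04 and adjusted p = 0.248 with an estimated correlation. Ketone body metabolism had 0 of 7 and 3 higher adjusted over the list alone (median 0.3, camera adjusted p = 0.0657). Cpt1a had 286 ± 47.5 against 168 ± 77.3 TPM (log2 fold change 0.86, adjusted p = 0.486). De novo lipogenesis had 1 of 19 lower, Scd1, with a median of 0.0463 and a mean of -0.191, camera adjusted p = 3.78e-04 downwards and adjusted p = 0.326 with an estimated correlation. Its median turned to -0.191 with quantile normalization and -0.187 with median centring. The median of malonyl-CoA and malonylation, 0.203 with 0 of 7 passing, turned to -0.0213 and -0.0302 in the same order. Acaca had 11.7 ± 1.90 against 11.8 ± 4.33 TPM (log2 fold change 0.05, SE 0.25, adjusted p = 0.925), Fasn -0.20 (adjusted p = 0.719), Mlycd 0.34 (adjusted p = 0.486) and Sirt5 0.20 (adjusted p = 0.548). Male-biased liver genes had a median of -0.377 with 0 of 13 passing, camera adjusted p = 4.62e-10 and adjusted p = 0.136 with an estimated correlation. Cholesterol synthesis had a median of 0.449 with 0 of 25 passing and 25 above 0 (camera adjusted p = 0.00428, adjusted p = 0.832 with an estimated correlation). Camera called acute phase response (median -0.0655, adjusted p = 1.23e-06), lipoproteins and sterol export (0.035, adjusted p = 3.75e-04), endoplasmic reticulum stress (-0.0342, adjusted p = 0.00801) and bile acid synthesis (0.0415, 1 of 17 lower, adjusted p = 0.0113) lower than the other genes, with adjusted p = 0.248, 0.136, 0.553 and 0.412 with an estimated correlation. Marker sets apart, fry passed for no gene list that camera called here (adjusted p from 0.0751 to 0.905). Markers of B and plasma cells (median -0.475, camera adjusted p = 1.63e-07), T and NK cells (-0.375, adjusted p = 1.18e-05) and red blood cells (-0.331, adjusted p = 2.16e-06) had adjusted p = 0.136 with an estimated correlation. Camera also called markers of hepatocytes lower (median -0.0527, 7 of 10 below 0, adjusted p = 0.00248), those of sinusoidal endothelial cells higher (0.408, adjusted p = 0.037) and the 1 tested marker of exocrine pancreas lower (adjusted p = 0.0302), with adjusted p = 0.248, 0.832 and 0.248 with an estimated correlation. Markers of resident macrophages had a median of 0.335 (camera adjusted p = 0.965), and without ketogenic-alternating replicate 4 a median of 0.695 (adjusted p = 4.3e-04).

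**Figure D2:**
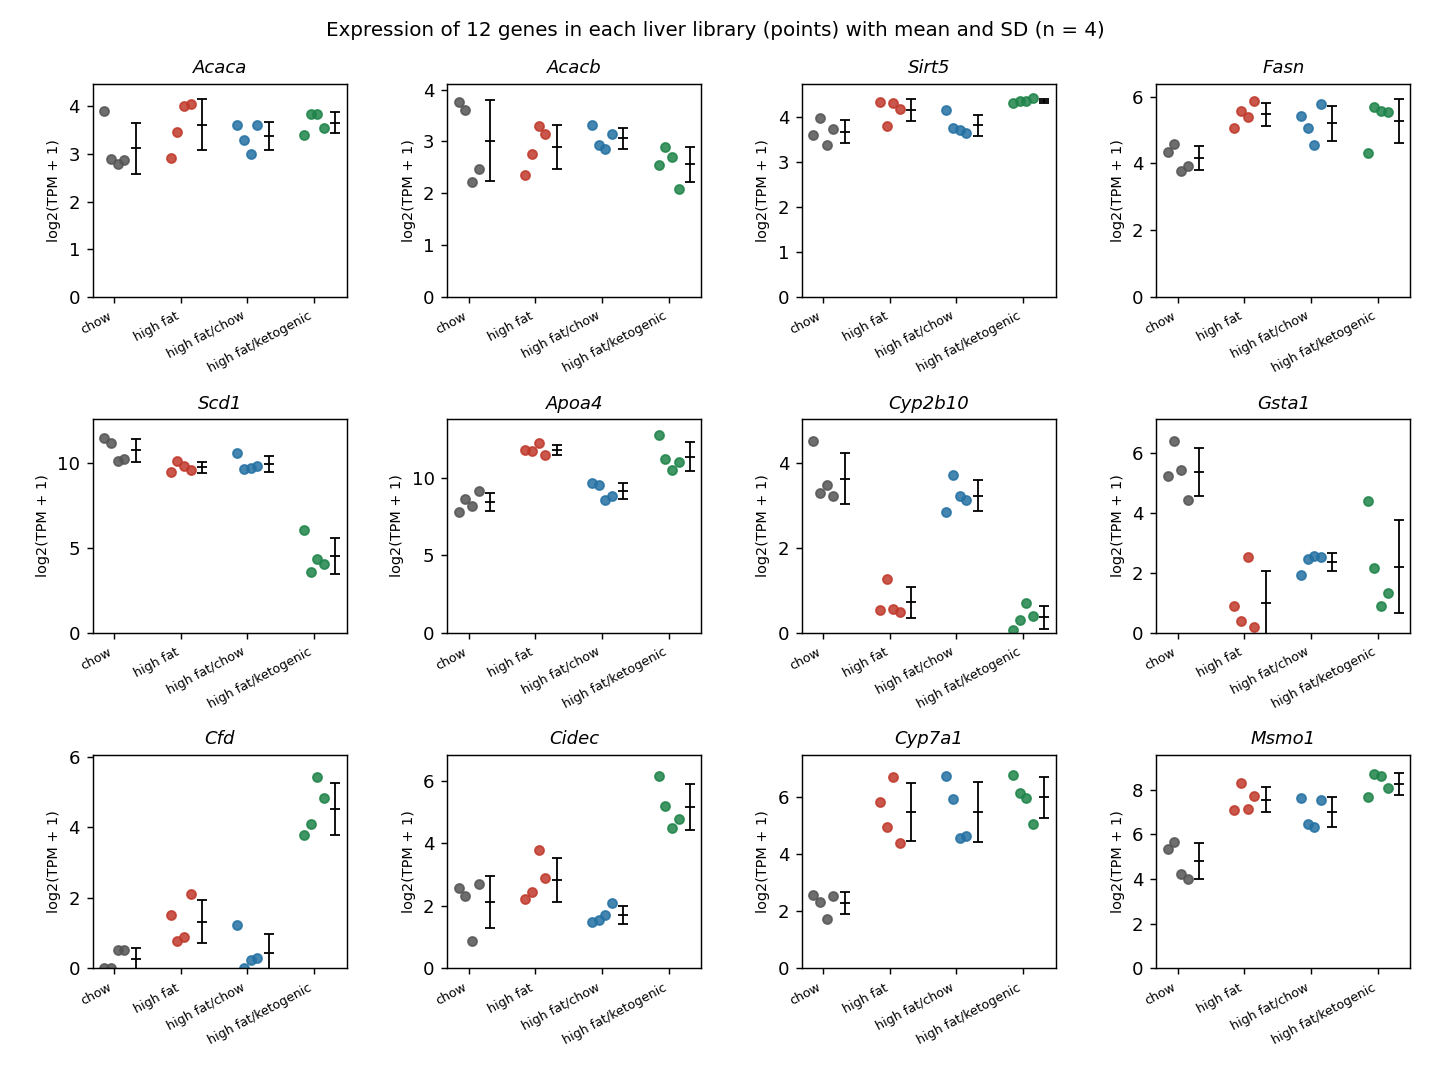
Expression of 12 genes as log2(TPM + 1) on axes from 0, with 1 point per library, 4 libraries per diet group, and horizontal bars and whiskers for mean and SD, where whiskers below 0 end at the axis. Scd1 averaged 28.3 TPM in the ketogenic-alternating group and 886 TPM in the high-fat group, and Acaca averaged 11.7 and 11.8 TPM.

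The comparison of the 2 alternating groups asked how ketogenic intervals differed from chow intervals. In the ketogenic-alternating group 16 of 29 members of fatty acid oxidation, 8 of 22 of triglyceride storage, 4 of 7 of ketone body metabolism and 10 of 15 of the interferon response were higher, and 6 of 18 of endoplasmic reticulum stress and 4 of 16 P450 enzymes were lower, with 1 P450 enzyme higher. Camera called these 6 lists, and with an estimated correlation every call was lost (adjusted p from 0.163 to 0.285). Cfd rose from 0.435 ± 0.608 to 24.6 ± 13.2 TPM (SD, n = 4; log2 fold change 4.10, SE 0.358, adjusted p = 3.58e-04). Cidec (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), which fuses lipid droplets, rose from 2.32 ± 0.662 to 38.6 ± 22.4 TPM (log2 fold change 3.44, adjusted p = 3.7e-04), and Fgf21, a hormone of fasting, from 3.43 ± 1.03 to 37.6 ± 24.0 TPM (adjusted p = 0.0089). Scd1 fell from 1041 ± 363 to 28.3 ± 25.8 TPM (log2 fold change -5.44, SE 0.446, adjusted p = 3.27e-04), and Hamp2 (-3.35, adjusted p = 9.24e-04), Cyp2b10 (-2.87, adjusted p = 1.41e-04), Cyp2c70 (-2.16, adjusted p = 1.41e-04) and Cyp2c29 (-1.93, adjusted p = 0.00294) fell. Krt23, a keratin, rose by 2.80 (adjusted p = 3.28e-04) and Osbpl3, an oxysterol-binding protein relative, by 2.22 (adjusted p = 0.00347). Apoa4 rose by 2.23 (adjusted p = 0.0166), with adjusted p = 0.0504 without chow-alternating replicate 3. Of 11002 genes tested, 86 were called, 68 higher and 18 lower, and 554 passed with no fold limit, 474 higher and 80 lower. The median of all genes was 0.19 higher, and median centring gave 35 higher and 38 lower calls, while quantile normalization gave 37 and 30. With no fold limit, median centring gave 108 higher and 194 lower, which turned the balance, quantile normalization 158 and 122, the fit of all 16 libraries 71 and 26, and the replicate number as a block 147 and 34, so the numbers of list members below depend on the fit. The count became 174 without ketogenic-alternating replicate 4, 57 without ketogenic-alternating replicate 2 and 52 without chow-alternating replicate 2, and with no fold limit 2513, 162 and 167 in the same order.

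In fatty acid oxidation, 16 of 29 members rose (22 adjusted over the list alone), with a median of 0.63, camera adjusted p = 5.48e-09, adjusted p = 0.24 with an estimated correlation and fry adjusted p = 0.00741. Vnn1, a target of the fatty acid sensor PPAR alpha, rose by 1.74 (adjusted p = 5.22e-04), and the acyl-CoA dehydrogenases Acadm and Acadl by 0.86 (adjusted p = 0.00329) and 0.71 (adjusted p = 0.00643). Cpt1a rose from 145 ± 26.3 to 286 ± 47.5 TPM (adjusted p = 0.00914). In triglyceride storage, 8 of 22 rose (11 adjusted over the list alone), with a median of 0.437, camera adjusted p = 0.00117 and adjusted p = 0.163 with an estimated correlation. Cd36, a fatty acid transporter, rose from 21.0 ± 7.05 to 78.6 ± 16.0 TPM (adjusted p = 0.00294), and the monoglyceride lipase Mgll (0.70, adjusted p = 0.0113) and the hormone-sensitive lipase Lipe (0.64, adjusted p = 0.0117) rose as well. In ketone body metabolism, 4 of 7 rose (4 adjusted over the list alone), with camera adjusted p = 0.0116 and adjusted p = 0.285 with an estimated correlation. Bdh1, which forms beta-hydroxybutyrate, rose from 139 ± 19.9 to 323 ± 16.3 TPM (adjusted p = 3.7e-04). Fry gave adjusted p = 8.22e-04 for triglyceride storage and 0.00741 for ketone body metabolism. The medians of these 3 lists stayed above 0 with quantile normalization and median centring.

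In de novo lipogenesis, 2 of 19 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of 0.114 and a mean of -0.0528, camera adjusted p = 0.327, and medians of -0.0731 with quantile normalization and -0.0948 with median centring. Fads2, a desaturase of polyunsaturated fatty acids, rose by 1.35 (adjusted p = 0.00914), whereas Scd1 fell. In malonyl-CoA and malonylation, 2 of 7 rose (3 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.529. Acsf3, which makes malonyl-CoA in mitochondria, rose from 18.6 ± 2.45 to 32.2 ± 3.69 TPM (adjusted p = 0.00848). Sirt5, which removes malonyl groups from proteins, rose from 13.1 ± 2.38 to 19.4 ± 0.700 TPM (log2 fold change 0.54, adjusted p = 0.0326). Its call was lost without ketogenic-alternating replicate 1, 2 or 3 or chow-alternating replicate 2, 3 or 4, with adjusted p up to 0.1. Acaca had 11.7 ± 1.90 against 9.55 ± 2.09 TPM (log2 fold change 0.28, adjusted p = 0.267), Acacb -0.50 (adjusted p = 0.111), Fasn 0.08 (adjusted p = 0.884), Mlycd 0.06 (adjusted p = 0.589) and Srebf1 0.53 (adjusted p = 0.12).

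In the interferon response, 10 of 15 tested members rose (12 adjusted over the list alone), with a median of 0.805, camera adjusted p = 1.15e-06, adjusted p = 0.24 with an estimated correlation and fry adjusted p = 0.00382. Usp18, Isg15 and Ifit3, induced by interferon, rose by 1.40 (adjusted p = 7.24e-04), 1.21 (adjusted p = 0.0056) and 1.23 (adjusted p = 0.00772). In endoplasmic reticulum stress, 6 of 18 fell (8 lower and 2 higher adjusted over the list alone), with a median of -0.34, camera adjusted p = 4.76e-11 and adjusted p = 0.163 with an estimated correlation. The chaperone Hspa5 fell from 337 ± 31.5 to 179 ± 28.7 TPM (adjusted p = 0.00347). Among xenobiotic P450 enzymes, 4 of 16 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.4, camera adjusted p = 3.39e-10 and adjusted p = 0.163 with an estimated correlation. Cyp3a11 fell by 1.19 (adjusted p = 0.00864). In NRF2 and glutathione, 4 of 14 rose and 2 fell (7 and 3 adjusted over the list alone), with a median of 0.298 and camera adjusted p = 0.552 downwards. In cholesterol synthesis, 4 of 25 rose (10 adjusted over the list alone), with a median of 0.616, camera adjusted p = 0.0112 and adjusted p = 0.703 with an estimated correlation. Camera also called acute phase response (median -0.291, 1 of 17 lower, adjusted p = 1.4e-08), amino acid catabolism (-0.116, 1 of 20 higher and 1 lower, adjusted p = 5.5e-05), immediate early and heat shock genes (-0.224, 1 of 14 higher and 1 lower, adjusted p = 1.07e-04), male-biased liver genes (-0.119, 0 of 13, adjusted p = 1.41e-04), oxidative phosphorylation (-0.0101, 0 of 22, adjusted p = 0.0028) and bile acid synthesis (0.0566, 1 of 17 higher and 3 lower, adjusted p = 0.0112) lower than the other genes. With an estimated correlation these had adjusted p from 0.163 to 0.475. Fry did not pass for endoplasmic reticulum stress (adjusted p = 0.0697), P450 enzymes (0.0775), cholesterol synthesis (0.213) or these 6 lists (0.319 to 0.992). The acute phase protein Orm1 fell by 0.99 (adjusted p = 0.0127) and the clock repressor Cry1 by 0.87 (adjusted p = 0.0119). Abcb4, which exports phospholipid into bile, rose by 0.81 (adjusted p = 0.00548), Pcx, pyruvate carboxylase, by 0.66 (adjusted p = 0.00923) and Ldha, lactate dehydrogenase, by 0.88 (adjusted p = 0.00347).

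Camera placed markers of hepatocytes below the other genes in the ketogenic-alternating group against the chow-alternating group. None of 10 passed over all genes and 4 fell adjusted over the list alone, with a median of -0.285, camera adjusted p = 5.48e-09 and adjusted p = 0.0216 with an estimated correlation. The median of all genes was 0.19 higher. The 20 highest genes held 27.08% to 29.47% of TPM in ketogenic-alternating libraries and 29.82% to 31.46% in chow-alternating libraries. By itself, a smaller share of those genes raises the TPM of all others, so it would not lower a marker outside the 20. A marker among the 20 would be part of the smaller share. Which hepatocyte markers were among them was not examined. Markers of sinusoidal endothelial cells had 2 of 12 higher (9 adjusted over the list alone), with a median of 0.608, camera adjusted p = 0.00208 and adjusted p = 0.475 with an estimated correlation. Oit3, 1 of these, rose from 8.06 ± 1.18 to 14.9 ± 2.24 TPM (adjusted p = 0.0106). Resident macrophage markers had a median of 0.775 with 0 of 11 passing (camera adjusted p = 0.0471, adjusted p = 0.703 with an estimated correlation), stellate cell markers 0.451 (camera adjusted p = 0.169) and red blood cell markers -0.865 (camera adjusted p = 1.25e-05, adjusted p = 0.24 with an estimated correlation). Markers of B and plasma cells had a median of -0.329 (camera adjusted p = 6.42e-04, adjusted p = 0.24 with an estimated correlation). Of adipocyte markers, 1 of 3 tested, Cfd, rose.

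**Figure D3:**
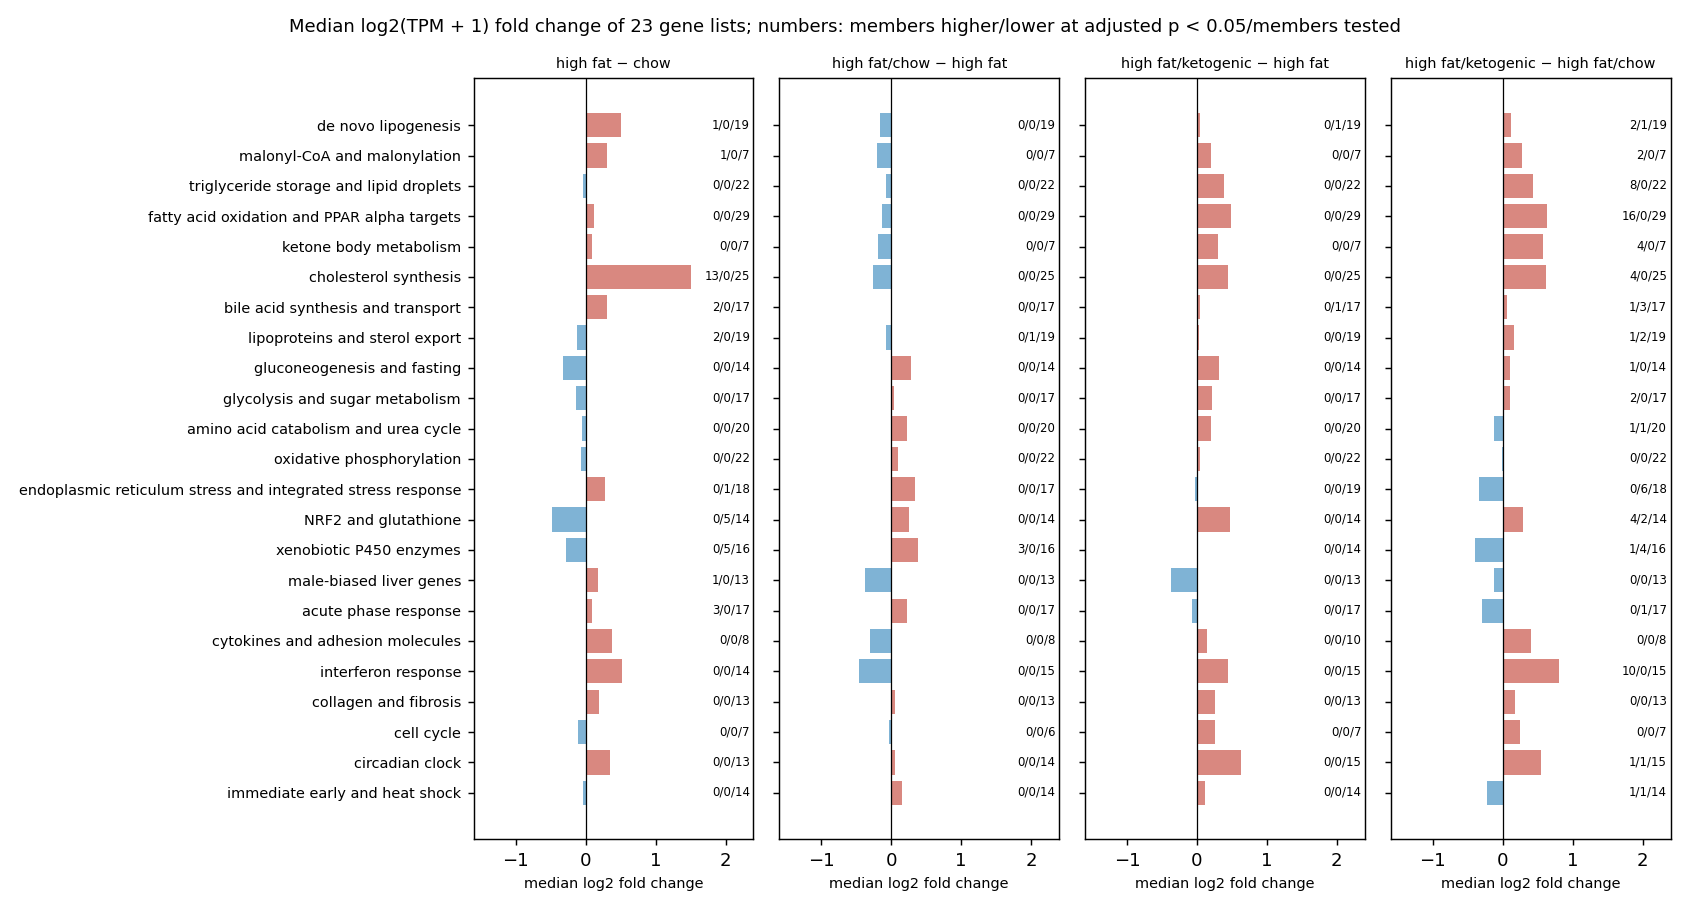
Median log2(TPM + 1) fold change of 23 gene lists in 4 comparisons (horizontal, 4 libraries against 4), with the members higher, lower and tested beside each bar. Cholesterol synthesis has a median of 1.51 in high fat against chow and fatty acid oxidation has 0.63 between the alternating groups, where the median of all genes was 0.19; medians of de novo lipogenesis in both ketogenic comparisons turn negative with quantile normalization and median centring.

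The chow-alternating group was compared with chow to ask what remained of the response to fat. Saa1 rose from 38.6 ± 18.8 to 598 ± 337 TPM (SD, n = 4; log2 fold change 3.87, adjusted p = 0.00516), Cyp7a1 by 3.17 (adjusted p = 0.00749) and Dbp, a clock output factor, by 3.06 (adjusted p = 0.0104). Gsta1 fell by 3.01 (adjusted p = 0.00446), Gsta2 by 1.91 (adjusted p = 0.011), Spaca6 by 1.85 (adjusted p = 0.00666) and Cyp26a1 by 1.75 (adjusted p = 0.00676). In cholesterol synthesis, 9 of 25 rose (22 adjusted over the list alone), with a median of 1.28, camera adjusted p = 3.71e-29 and adjusted p = 0.294 with an estimated correlation; Mvd rose by 2.39 (adjusted p = 0.0142). In NRF2 and glutathione, 6 of 14 fell (6 adjusted over the list alone), with camera adjusted p = 5.39e-07 and adjusted p = 0.294 with an estimated correlation. In endoplasmic reticulum stress, 2 of 17 rose (10 higher and 1 lower adjusted over the list alone), with camera adjusted p = 9.29e-10 and adjusted p = 0.294 with an estimated correlation. Acute phase response had 3 of 17 higher (median 0.329, camera adjusted p = 1.06e-07), bile acid synthesis 2 of 17 higher (0.245, adjusted p = 1.74e-05) and circadian clock 2 of 15 higher and 1 lower (0.523, adjusted p = 0.0197), each with adjusted p = 0.416 with an estimated correlation. Of xenobiotic P450 enzymes, 3 of 16 rose and 1 fell (median 0.247, camera adjusted p = 0.0531), where 5 fell in high fat against chow. Cyp2e1 passed in 1, Cyp2c50 in 2, Cyp2c54 in 4 and Cyp3a11 in 6 of the 8 fits that each left out 1 library. Their limma adjusted p reached 0.139, 0.123, 0.063 and 0.0515 in the same order, so these P450 calls depended on single libraries. Camera also called de novo lipogenesis (0.273, adjusted p = 0.00769), male-biased liver genes (0.274, 1 of 13 higher, adjusted p = 0.0266) and malonyl-CoA and malonylation (0.141, adjusted p = 0.0347) higher, with adjusted p from 0.66 to 0.713 with an estimated correlation. Marker sets apart, fry passed for no gene list that camera called here. Its adjusted p was 0.121 for cholesterol synthesis, 0.121 for endoplasmic reticulum stress, 0.0517 for NRF2 and glutathione and 0.254 to 0.626 for the others. Among cell type markers, camera called those of neutrophils (median 0.486 over 3 tested, adjusted p = 0.0174) and red blood cells (0.605, adjusted p = 0.00135) higher, with adjusted p = 0.314 and 0.416 with an estimated correlation. Selenbp2 rose by 2.88 (adjusted p = 0.00749) and the plasma protein Ahsg by 0.87 (adjusted p = 0.00769). Of 10862 genes tested, 67 were called, 40 higher and 27 lower. The count was 29, 39, 35 and 35 without chow-alternating replicates 1, 2, 3 and 4, 44 without chow replicate 2 and 34 without chow replicate 4, and 2 with no filter on low values.

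The ketogenic-alternating group was compared with chow in the same way. Scd1 fell from 1894 ± 863 to 28.3 ± 25.8 TPM (SD, n = 4; log2 fold change -6.24, SE 0.477, adjusted p = 1.35e-04), Hamp2 by 4.69 (adjusted p = 0.00101) and Cyp2b10 by 3.27 (adjusted p = 1.84e-04). Dbp rose from 2.68 ± 1.60 to 89.9 ± 52.7 TPM (adjusted p = 1.35e-04), Cfd by 4.27 (adjusted p = 1.35e-04), Cyp7a1 by 3.69 (adjusted p = 1.84e-04) and Idi1 by 3.62 (adjusted p = 0.00139). In cholesterol synthesis, 23 of 25 members rose (23 adjusted over the list alone), with a median of 1.89, camera adjusted p = 8.56e-21, adjusted p = 0.583 with an estimated correlation and fry adjusted p = 0.0162. In circadian clock, 9 of 16 rose and 3 fell (9 and 4 adjusted over the list alone), with a median of 1.1 and camera adjusted p = 0.0607. Per3 rose by 2.06 (adjusted p = 4.62e-04) and Tef by 1.68 (adjusted p = 0.00136), whereas Cry1 fell by 1.94 (adjusted p = 0.00151). In the interferon response, 8 of 15 rose (12 adjusted over the list alone), with a median of 0.964, camera adjusted p = 1.59e-06 and adjusted p = 0.583 with an estimated correlation. Markers of resident macrophages (median 0.913, 11 of 11 above 0, adjusted p = 0.0406), stellate cells (0.523, adjusted p = 0.0496), sinusoidal endothelial cells (0.49, adjusted p = 0.0496) and adipocytes (0.755 over 3 tested, adjusted p = 0.0375) were called higher by camera as well, with adjusted p from 0.583 to 0.725 with an estimated correlation. Fatty acid oxidation had 8 of 29 higher (camera adjusted p = 0.00199, adjusted p = 0.725 with an estimated correlation), and NRF2 and glutathione 5 of 14 lower (camera adjusted p = 6.94e-04, adjusted p = 0.583 with an estimated correlation). Triglyceride storage (4 of 22 higher, camera adjusted p = 0.0496), ketone body metabolism (3 of 7 higher, adjusted p = 0.0406), malonyl-CoA and malonylation (2 of 7 higher, adjusted p = 0.0496) and xenobiotic P450 enzymes (4 of 16 lower and 2 higher, adjusted p = 0.0406 downwards) were called too, each with adjusted p = 0.725 with an estimated correlation. Fry gave adjusted p = 0.0135 for the interferon response and 0.0305 for ketone body metabolism. It gave 0.0795 to 0.165 for the other gene lists that camera called, cholesterol synthesis and marker sets apart. Of 11091 genes tested, 257 were called, 194 higher and 63 lower, and the median of all genes was 0.15 higher. The count was 470 without chow replicate 1, 149 without ketogenic-alternating replicate 2, 151 without ketogenic-alternating replicate 3 and 140 without the libraries over 33%, and median centring gave 122 higher and 101 lower.

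Responses to an alternating diet were set against the response to high fat, with the high-fat libraries shared. Of 109 genes passing with no fold limit in high fat against chow and 5 in chow-alternating against high fat, among 10806 tested in both, 5 passed in opposite directions, where independent calls would give 0.0117 and 0.0128 for the 2 directions. These were Cyp2b10, Cyp2c29, Cyp2c55, Apoa4 and Fabp2. In 100 simulated draws without effect, the high-fat group was shared alike and deviations of the 16 libraries were drawn with replacement. The median was 0 and 1 draw reached 5 or more, with 915 genes. These draws hold no effect in any group, so they do not show what shared libraries give when 109 genes pass. The overlap of 5 cannot be judged by them. With the high-fat libraries divided 2 and 2, the median was 1.5 (0 to 6). Fold changes across genes correlated at r = -0.559 (simulated -0.469), and at -0.191 (-0.213 to 0.0585) with divided libraries. For the ketogenic-alternating group the overlap was 0 of 108 and 3 genes, with r = -0.144 (simulated -0.463) and 0.105 with divided libraries. Between the 2 alternating groups against high fat, 0 genes passed in both, with r = 0.242 (simulated 0.439) and -0.167 with divided libraries.

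Transcripts of acetyl-CoA carboxylase were compared because the gene product is the study's subject. For Acaca, ENSMUST00000103201 (56 exons) held 49.77% and ENSMUST00000020843 (54 exons) 42.47% of the gene total over all libraries, and for Acacb, ENSMUST00000102582 held 66.81% and ENSMUST00000031583 31.11%. The first Acaca transcript held 21.7% ± 25.5 (SD, n = 4) of the total in the ketogenic-alternating group and 77.1% ± 24.5 in the high-fat group (exact two-sided permutation p = 0.05714, adjusted p = 0.4571). None of 24 exact permutation tests passed. The smallest p that 4 against 4 allows is 0.02857, so at least 14 of the 24 would have had to reach it for any to pass after adjustment, and the tests decide nothing about a change of the shares. The files hold mRNA only, so malonylation of the protein was not analysed here.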

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

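The tests of the abundant genes, the collection hour, the cholesterol list against Dbp and the adipose transcripts were chosen only after the result was seen, and so were the counts with the length trend removed.

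For each library measure and named gene, the highest or lowest of the 4 libraries of a group was tested by Dixon's ratio, with a critical value of 0.829. The ratio is the gap to the nearest library over the range of the 4. For genes it was taken on log2(TPM + 1), whereas TPM and the mean of the others are given below as description. Of 588 values tested in this way, over 141 named genes and the library measures, 34 gene values and 1 library measure stood apart, where chance alone gives about 29.4 at 1 in 20. Ketogenic-alternating replicate 1 had 15557 genes above 0, against a mean of 14710 in the others of its group. In chow replicate 1, Acaca at 14 TPM (mean of the others 6.24) stood apart. In chow replicate 3, Hadh at 190.2 TPM (mean of the others 279) stood apart. In chow replicate 4, Fgf21 at 8.7 TPM (mean of the others 5.61) stood apart. In chow-alternating replicate 1, Pck1 at 534 TPM (mean of the others 1610.7), Mfsd2a at 9.21 TPM (mean of the others 38.1), Gstm2 at 112 TPM (mean of the others 73.8) and Slc22a7 at 51.1 TPM (mean of the others 31.2) stood apart. In chow-alternating replicate 2, Pparg at 3.15 TPM (mean of the others 5.2), Cpt1a at 106 TPM (mean of the others 158), Acadl at 159 TPM (mean of the others 187) and Hadhb at 111 TPM (mean of the others 143) stood apart. In chow-alternating replicate 4, Tef at 80.5 TPM (mean of the others 42.9), Pdia4 at 98.9 TPM (mean of the others 123), Slc27a5 at 759 TPM (mean of the others 657) and Dbp at 83.4 TPM (mean of the others 19.2) stood apart. In high-fat replicate 1, Dnajb9 at 22.1 TPM (mean of the others 47.3), Acat1 at 189 TPM (mean of the others 307) and Acadm at 284 TPM (mean of the others 388) stood apart. In high-fat replicate 2, Cyp2b10 at 1.39 TPM (mean of the others 0.448) stood apart. In high-fat replicate 3, Ahsg at 13087.8 TPM (mean of the others 6741.1), Egr1 at 79.5 TPM (mean of the others 2.74), Cyp7b1 at 92.1 TPM (mean of the others 214), Cyp3a59 at 33.9 TPM (mean of the others 16.7) and Slc39a4 at 11.1 TPM (mean of the others 6.66) stood apart. In ketogenic-alternating replicate 1, Slc10a1 at 507 TPM (mean of the others 735), Fasn at 18.7 TPM (mean of the others 47.3), Lcn2 at 121 TPM (mean of the others 11.8), Gpat3 at 18.3 TPM (mean of the others 8.71), Nsdhl at 38.3 TPM (mean of the others 90.1), Saa2 at 161 TPM (mean of the others 19.2) and Mup20 at 11609.1 TPM (mean of the others 7954.5) stood apart. In ketogenic-alternating replicate 3, Hyou1 at 37.3 TPM (mean of the others 22) and Gstm1 at 807 TPM (mean of the others 1048.4) stood apart. In ketogenic-alternating replicate 4, Ucp2 at 14.2 TPM (mean of the others 21.9) stood apart.

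Whether chance division of the libraries gives as many calls was tested over the 35 divisions of each comparison's 8 libraries into 4 and 4, the real one included. Only the real division reached its count for ketogenic-alternating against chow-alternating (86 genes, 1 of 35, highest other 1) and for chow-alternating against chow (67 genes, 1 of 35, highest other 1). First of 35 is the strongest result this test can give, and it was not adjusted for the 6 comparisons. It argues against chance in these comparisons without excluding it, and it cannot tell diet from other differences between the groups. Other divisions called as many genes for high fat against chow (95 genes, 2 of 35 divisions as large, highest other 167), chow-alternating against high fat (4 genes, 2 of 35, highest other 5), ketogenic-alternating against high fat (4 genes, 3 of 35, highest other 6) and ketogenic-alternating against chow (257 genes, 2 of 35, highest other 259). By the rule set beforehand, the counts of these comparisons are ones that chance division could give. The division that called 259 set chow replicate 1 with ketogenic-alternating replicates 1 to 3, whose values rose with transcript length (rho 0.23 to 0.424), against the 4 libraries in which they fell. The division that called 167 set chow replicates 1 and 4 with high-fat replicates 3 and 4. Both point to a structure of the libraries apart from diet. With the length trend removed, high fat against chow called 93 genes with 85 in the highest other division, and ketogenic-alternating against chow called 246 with 201.

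The 2 alternating groups differed from each other by 86 called genes in their direct comparison, 68 higher and 18 lower with ketogenic intervals, on a median shift of all genes of 0.186. A smaller share of TPM in a few abundant genes was argued against as the whole cause of that shift, because the 20 highest genes lifted all others by 0.0461 (SE 0.0125), although the 1000 highest gave 0.172 as a set. A trend on transcript length stays open, with a median of 0.0942 in the shortest genes and 0.252 in the longest, and its removal left 89.3% of changed genes higher against 85.6% before, a check that cannot remove a shift of a whole library. With median centring 35.8% were higher, so whether more genes rose than fell depends on the scaling. An effect of the ketogenic diet on many genes at the same time is a candidate explanation that these values cannot separate from scaling.

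Clock genes of opposite phase differed between the ketogenic-alternating group and chow: 10 genes that peak with Dbp had a median of 1.58 and 5 that peak with Arntl had -1.38, a distance of 2.97. The 2 medians also had opposite signs in the other groups fed high fat. In high fat against chow 7 tested genes had 0.855 and 5 had -0.809, a distance of 1.66, and in chow-alternating against chow 9 had 1.08 and 5 had -0.921. In high fat against chow, 0 of 13 members of the circadian clock list passed over all genes, and 3 were higher and 2 lower adjusted over the list alone. The comparisons share the chow libraries, so another clock phase in chow alone would give the pattern in each, and they are not independent repeats. The sets of tested genes differ, and the distances were not tested against each other. Collection at another hour of the day and a clock shifted by diet cannot be told apart, since the labels give no hour and either gives such distances. Clock genes also differed between groups fed high fat, which another phase in chow alone would not give. Between the alternating groups Cry1 fell and passed in all 8 fits that each left out 1 library (limma adjusted p up to 0.0472). Bhlhe41 was tested in 4 of these fits and passed in 3. In ketogenic-alternating against high fat, 0 of 15 clock members passed over all genes (median 0.625, camera adjusted p = 0.776). The hours of these groups are unknown as well. If the hour of collection also moved cholesterol synthesis, libraries of a group with more Dbp might have more of it. This stays open. Deviations from the group means of the 25 cholesterol genes and of Dbp had r = 0.0666 (95% interval -0.503 to 0.596, permutation p = 0.803, 1e+05 resamples; rho = -0.112, p = 0.673) over 16 libraries, and r = -0.00427 without the 2 farthest. The interval is wide, and deviations within groups hold no difference in hour between groups.

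Cfd and Cidec, known from adipocytes, were higher in the ketogenic-alternating group than in the chow-alternating group, Cfd by 24.2 TPM. Adipose tissue in the samples was argued against, because Adipoq, Plin1, Lep and Retn together differed by -0.007 TPM, or -0.0289% of the difference in Cfd. In the ketogenic-alternating group Adipoq averaged 0.0231 TPM, Plin1 0.00776, and Lep and Retn 0. A change of these genes within liver cells with the ketogenic intervals is a candidate explanation, found and tested on the same data, and no cell was separated here.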

How the results depend on the processing

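The fits with median centring, with the length trend removed and without the libraries over 33% in 20 genes were chosen only after seeing the data. Leaving out 1 library moved the counts of called genes to 36 to 114 in high fat against chow, 3 to 29 in chow-alternating against high fat, 2 to 21 in ketogenic-alternating against high fat, 52 to 174 between the alternating groups, 29 to 94 in chow-alternating against chow and 149 to 470 in ketogenic-alternating against chow. High-fat replicate 3 gave the values of 114, 29 and 21, and chow replicate 4 that of 36. High-fat replicates 1 and 2 each gave 2, chow-alternating replicates 2 and 1 gave 52 and 29, ketogenic-alternating replicates 4 and 2 gave 174 and 149, and chow replicate 1 gave 94 and 470. The overlaps moved to 2 to 28, 0 to 4 and 0 to 3, each highest without high-fat replicate 3. With no filter on low values, counts were 40 in high fat against chow, 1 in ketogenic-alternating against high fat, 57 between the alternating groups and 2 in chow-alternating against chow, with more genes tested. With all 16 libraries in 1 fit they were 8 in ketogenic-alternating against high fat and 55 between the alternating groups, and 3 for the overlap of high fat with chow-alternating. Without the libraries over 33% in 20 genes, counts were 19 in high fat against chow, 1 in chow-alternating against high fat and 140 in ketogenic-alternating against chow, and 0 for that overlap, with fewer libraries. That overlap was 2 with the length trend removed and 1.5 with the high-fat libraries divided. Median centring gave 7 in ketogenic-alternating against high fat. With no fold limit counts were 554 between the alternating groups, 126 in chow-alternating against chow and 555 in ketogenic-alternating against chow. The replicate number as a block gave 43 in high fat against chow and 11 in chow-alternating against high fat, but numbers did not pair libraries: 4 of 16 matched their own number best, and same-number correlations ran from -0.580 to 0.386. Unless stated, the cause was not tested.

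Camera's direction turned in 3 lists. Without the libraries over 33%, gluconeogenesis and fasting had a median of -0.00992 (adjusted p = 0.956) and male-biased liver genes -0.114 (adjusted p = 0.165) in chow-alternating against high fat, where both had been called. Resident macrophage markers in ketogenic-alternating against high fat, not called in the fit of 8 libraries, ranged from 0.113 to 0.695 on leaving out 1 library, and were called (adjusted p = 4.3e-04) without ketogenic-alternating replicate 4. Sign changes of values that no setting called, 479 in number, are not counted here. No named gene reversed. Over 510 gene results, of which 219 passed, leaving out 1 library kept 3612 values on their side of the threshold, 409 lost and 19 gained a call, and other settings kept 4237, with 327 lost and 17 gained. Over 206 list results, of which 91 passed camera, 90 lost their call with an estimated correlation, the exception being hepatocyte markers between the alternating groups. Alternatives that need counts (size factors, library totals and a count-based tool) were not run, and the unknown depth limits what can be said of genes near 1 TPM.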

Other observations

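The genes of this part were chosen only after their values were seen. In the ketogenic-alternating group against the chow-alternating group, Pparg, a fatty acid receptor that drives fat storage, rose from 4.69 ± 1.04 to 12.5 ± 1.71 TPM (SD, n = 4; log2 fold change 1.26, limma adjusted p = 0.00345), and Fabp2, a fatty acid binding protein, from 89.2 ± 8.80 to 264 ± 47.3 TPM (adjusted p = 3.28e-04). Ucp2, a mitochondrial carrier, rose from 8.64 ± 0.269 to 19.99 ± 3.90 TPM (adjusted p = 0.00347), the fatty acid transporter Slc27a1 by 1.02 (adjusted p = 0.00719) and Elovl2, which lengthens polyunsaturated fatty acids, by 1.01 (adjusted p = 0.00264). These 5 passed on leaving out any 1 of the 8 libraries. Mfsd2a, a lysophospholipid transporter, rose by 1.93 (adjusted p = 0.0257), but not without ketogenic-alternating replicate 2 or chow-alternating replicate 2 or 3 (adjusted p up to 0.0816). Gpat3, an enzyme of triglyceride synthesis, rose by 1.46 (adjusted p = 0.0176), but not without chow-alternating replicate 2 or 3 (adjusted p up to 0.058). Against chow, Pparg rose by 1.13 (adjusted p = 0.00308), Ucp2 by 1.16 (adjusted p = 0.00571) and Slc27a1 by 1.11 (adjusted p = 0.0103) in the ketogenic-alternating group. In the smaller fit without the libraries over 33% in 20 genes, Ucp2 (log2 fold change 1.05, adjusted p = 0.0527) and Slc27a1 (0.876, adjusted p = 0.0883) did not pass.

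Ces2a, a carboxylesterase, fell from 406 ± 47.1 TPM in chow to 132 ± 28.9 TPM in high fat (adjusted p = 0.00296) and 108 ± 21.7 TPM with ketogenic intervals (adjusted p = 1.84e-04), and passed on leaving out any 1 library of either comparison. G6pc, which releases glucose, fell by 1.71 with ketogenic intervals against chow (adjusted p = 0.0353), but not without any 1 of the 4 ketogenic-alternating replicates or chow replicate 2 or 4 (adjusted p up to 0.106). The metallothioneins Mt1, from 197 ± 147 to 910.1 ± 390 TPM (adjusted p = 0.0282), and Mt2 (adjusted p = 0.0292) rose with chow intervals against chow. Both lost their calls without chow-alternating replicate 1, 2 or 3 or chow replicate 2, Mt1 also without chow replicate 4 and Mt2 without chow-alternating replicate 4, with adjusted p up to 0.0929. In high fat against chow, Fabp2 rose from 79.9 ± 17.8 to 169 ± 12.9 TPM (adjusted p = 0.0148), but not without high-fat replicate 4 or chow replicate 4 (adjusted p up to 0.0588). Hdc, which makes histamine, fell by 1.88 (adjusted p = 0.044) and Acmsd, an enzyme of tryptophan breakdown, by 1.65 (adjusted p = 0.0266). Hdc passed in 2 and Acmsd in 1 of the 8 fits that each left out 1 library. Hdc failed without chow replicate 1, 3 or 4 or high-fat replicate 1, 3 or 4 (adjusted p up to 0.154), and Acmsd without any single chow replicate or high-fat replicate 1, 2 or 4 (adjusted p up to 0.0976). In the smaller fit without the libraries over 33%, Fabp2 (log2 fold change 1.18, adjusted p = 0.0676), Hdc (-2.16, adjusted p = 0.0722) and Acmsd (-1.55, adjusted p = 0.298) did not pass, nor did Mt2 with chow intervals (3.06, adjusted p = 0.0513).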
